A study of Mus musculus with 7 samples.

How the data were processed

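RNA-seq was done on mCherry-labelled 4T1 cells, a mouse triple-negative breast cancer line, sorted by flow cytometry from tumors in the mammary fat pads of BALB/c mice. The fat pads had received 100 µL of phosphate-buffered saline (PBS) or 0.3 units of Botox in the same volume 7 days before the tumor cells. The labels name a separate mouse for each of the 7 libraries, 3 after PBS and 4 after Botox, and groups and replicate numbers were taken from the sample titles. Per the labels' protocols, RNA was extracted with Trizol, depleted of ribosomal RNA and made into stranded libraries that were sequenced from both ends. The numbers of sorted cells, the amounts of RNA and the library dates are not given in the sources used here.

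The deposited expression table gives TPM for 57126 Ensembl genes, a unit of transcript abundance per length that has the same total in each library. Each TPM column exceeds the TPM total by 0.001 for each row, so the authors added a constant of 0.001 to every deposited value, and 0.001 stands for a gene with no reads. The length column equals stop minus start in every row, and the values show that TPM was made with this genomic span, introns included, as the gene length. Long genes with many introns therefore have low TPM, and short genes such as 7SL RNA have very high TPM. Per the submitters' processing notes, the genome build was mm39, and Bowtie2 2.2.5, SAMtools and DESeq2 were used, with no role or order stated. The read counter, its strand setting and its treatment of reads that map to several places are not given in the sources used here. The authors' deposited table of KEGG gene sets holds, per its header, a ratio of B to C, a signed fold change, p-values and a false discovery rate for 227 sets. B and C were read as Botox and control because they are the first letters of the column names of the expression table. That table names no genes, so the part of the rule below on the first genes of each KEGG set could not be applied.

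TPM carries no depth of its own. In each library, however, the deposited value minus 0.001, multiplied by the span, fell on multiples of 1 step, which is the size expected of 1 read. The step was found with a periodogram that recovered the known step in 2 of 2 simulated libraries. Among values under 20 reads, 87.9% to 89.9% lay within 0.1 of a whole number, against 20% by chance. Reads estimated this way totalled 8.57 to 13.6 M per library. Because not all values came out whole, the estimates were used to describe the libraries and not for a count test. Reads without molecular identifiers are not independent molecules.

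Genes with at least 1 TPM in at least 3 libraries (11260 genes, 7241 of them protein-coding) were tested on log2(TPM + 1) with limma 3.58.1 in R 4.3.3, using an intensity trend, two-sided tests and Benjamini-Hochberg adjustment at 0.05. Fold changes on this scale understate the change of genes with low values. The design held the group only. Gene lists, 40 in all with 895 entries of which 894 matched a symbol in the table, were written before the data were examined. They covered mitochondria, metabolism, stress, growth, tumor cell state, nerve signals, immune signaling, other cell types and RNA quality. The 31 lists with at least 5 tested members were tested with limma's camera at a preset correlation of 0.01, adjusted over the lists, with camera at an estimated correlation and fry beside it. Camera compares a list with all other genes, and fry asks whether the genes of a list move one way on balance. The share of TPM from the 13 protein genes of mitochondrial DNA (mtDNA) and other values per library were compared with exact two-sided permutation tests over the 35 arrangements of the libraries, for which the smallest p is 0.057. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 was used for the values per library.

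The rule for named genes was also fixed before the data were examined. It took the 12 genes with the largest fold change in each direction among those past the threshold with non-overlapping groups, leaving out predicted genes, pseudogenes named as such and unnamed IDs. Where fewer than 12 passed, it was filled up with the genes of smallest p that had a mean of at least 1 TPM in the higher group, described as not past the threshold. The 3 tested members with the smallest p of each list discussed, the mtDNA genes as a group and Snap25 completed it. Not every gene that the rule names is reported here. Which lists to discuss one by one, and which genes to plot, was chosen after the results were seen. Symbols with several IDs were matched to the protein-coding ID with the highest mean.

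The fit was tested on simulated data, 5 tables of 11260 genes with the gene means and library offsets of these libraries and 200 genes changed per table. Each gene had a single spread for all libraries, genes varied independently, and the changed genes were drawn from the better expressed ones. The shares below therefore do not cover libraries of unequal quality or weakly expressed genes. On the deposited scale it recovered 90.8% of genes lowered by 2 on the log2 scale in Botox and 15.6% of those lowered by 1. It recovered 28.4% of genes raised by 2 and 0% of those raised by 1. With median-of-ratios size factors the shares were 77.6%, 17.2%, 75.2% and 34.8%. Of unchanged genes, 0.17% and 0.056% were called on the 2 scales.

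Alternatives fixed before the data were examined were pseudocounts of 0.1 and 0.5, no filter, a filter of 5 TPM, median-of-ratios size factors, quantile normalization, removal of all genes of mtDNA, limma without trend, array weights, the replicate number as a block and each library left out in turn. Further alternatives were chosen after the data were seen. They left out Botox 2 and Botox 4 together, kept only protein-coding genes, removed the 7SL genes, or removed each library's trend with GC content and span by natural splines with 4 degrees of freedom per term. GC content was taken by Ensembl ID from the transcripts of an older mouse build, GRCm38, and 94.8% of tested genes had a value. No coordinates were taken from that build.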

Results

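Transcript levels were measured in 4T1 cells sorted from 7 mammary fat pad tumors, 3 grown after PBS and 4 after Botox, a botulinum toxin that blocks transmitter release from nerve endings and was used here to denervate the fat pad. The comparison asked how prior denervation changed the transcriptome of the cancer cells. Between 15625 and 25147 genes had a value above 0 per library. The mean was 24873 ± 438 (SD, n = 3) after PBS and 19714 ± 3746 (SD, n = 4) after Botox, with no overlap between the groups (exact permutation p = 0.057, the smallest the design allows; 0.183 after adjustment over 16 measures per library). The estimated depth was 11.6 ± 2.52 M reads after PBS (SD, n = 3; 8.75, 12.3 and 13.6 M in PBS 1 to 3) and 9.50 ± 0.917 M reads after Botox (SD, n = 4; 10.1, 10.5, 8.57 and 8.88 M in Botox 1 to 4).

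Small noncoding RNAs held most of the TPM, a unit that here divides by genomic span and so weights short genes. 7SL RNA, the RNA of the signal recognition particle, listed as Rn7s1 and Rn7s2 with nearly the same values, made up 50.3% ± 2.15 of TPM after PBS (SD, n = 3) and 61.3% ± 7.39 after Botox (SD, n = 4). Every Botox library lay above every PBS library (exact permutation p = 0.057, the smallest possible; 0.183 adjusted). Of estimated reads it took 9.03% ± 0.846 (SD, n = 3) and 15.8% ± 6.02 (SD, n = 4). 7SK RNA, which holds back the elongation factor P-TEFb, took 8.18% ± 0.763 (SD, n = 3) and 6.78% ± 2.82 (SD, n = 4). Nuclear protein-coding genes held 11.0% ± 0.634 of TPM after PBS (SD, n = 3) and 7.64% ± 3.13 after Botox (SD, n = 4), with 3.71% in Botox 4 and 11.2% in Botox 3. Processed pseudogenes held 16.3% ± 1.89 (SD, n = 3) and 10.9% ± 4.90 (SD, n = 4). Reads of a gene and its near-identical copies cannot be assigned with certainty, which applies to 7SL, ribosomal protein genes and mtDNA genes with nuclear copies.

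**Figure D1:**
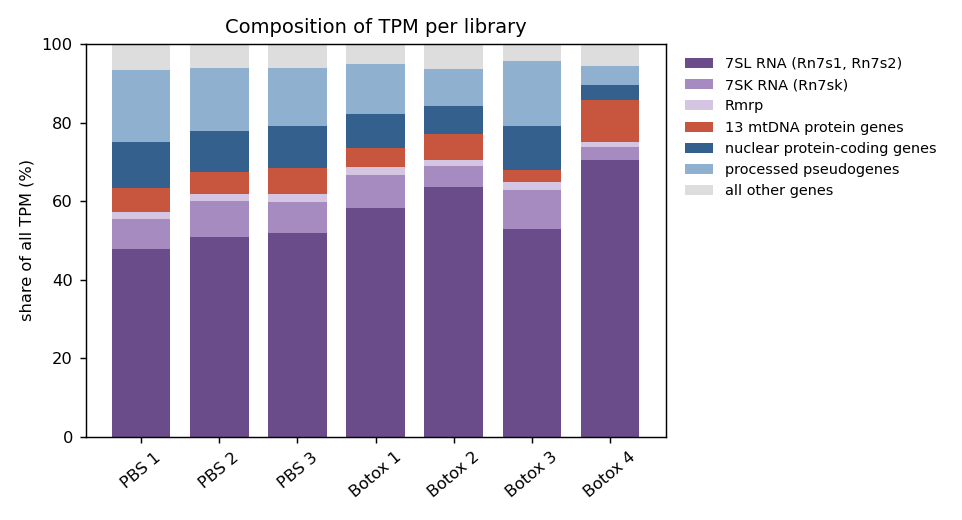
Share of all TPM (%) per library, stacked by class of gene. 7SL RNA makes up 47.9% to 52.0% of the PBS libraries and 53.04% to 70.4% of the Botox libraries.

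Botox 2 and Botox 4 differed from the rest in their weakest genes. In these 2 libraries 3.01% and 2.44% of the detected genes had 1 to 4 estimated reads, against 14.0% in Botox 3 and 20.4% to 23.8% in Botox 1 and the PBS libraries. All 7 libraries take part in the comparisons that follow unless one is named as left out.

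**Figure D2:**
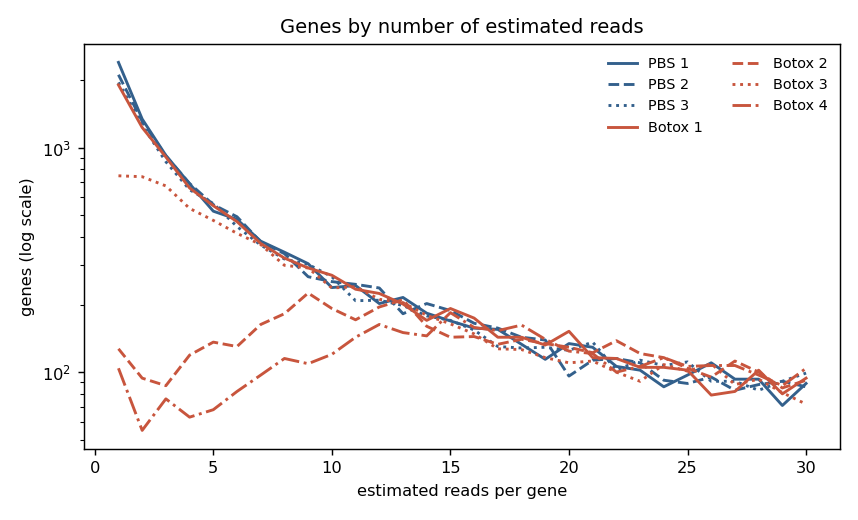
Genes (log scale) by estimated reads per gene, from 1 to 30, in each library. In Botox 2 and Botox 4 the most common number of reads is 9 and 15, while in the other 5 libraries it is 1.

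Genes of tumor cells and of macrophages were present in every library. Keratins 8 and 18 and vimentin had high TPM in both groups. Krt18 was at 155 ± 15.6 TPM (SD, n = 3) after PBS and 105 ± 54.97 TPM (SD, n = 4) after Botox, and Vim at 514 ± 18.4 and 345 ± 175 TPM. The epithelial genes Epcam and Cdh1 were at 2.82 ± 0.436 and 2.91 ± 0.454 TPM after PBS and 1.77 ± 0.323 and 1.72 ± 0.552 TPM after Botox. Lyz2, which encodes lysozyme, was at 336 ± 62.3 TPM (SD, n = 3) and 233 ± 167 TPM (SD, n = 4), with 81.4 TPM in Botox 1 and 465 TPM in Botox 2. Apoe was at 334 ± 100.98 and 177 ± 94.9 TPM. Both macrophage genes had higher mean TPM than Krt18 in both groups, and these values do not tell which cells a transcript came from. TPM here divides by genomic span, introns included, so it does not rank different genes by their number of transcripts. Outside macrophages, the highest markers of other cell types were Cd74, an antigen presentation gene of dendritic and other cells, at 33.2 ± 25.3 and 24.8 ± 12.1 TPM, the collagen gene Col6a1 at 16.1 ± 2.53 and 11.8 ± 8.52 TPM, and the globin gene Hba-a2 at 9.22 ± 3.63 and 4.84 ± 1.69 TPM. No marker of T or NK cells, B cells or adipocytes was high enough to be tested. The neutrophil genes S100a8 and S100a9 were at 1.72 ± 1.36 and 2.33 ± 1.44 TPM after PBS and 1.15 ± 1.46 and 0.533 ± 0.564 TPM after Botox. Neutrophil markers had too few tested members for a list test on the deposited scale, but they were called lower when only protein-coding genes were kept and rescaled (camera adjusted p = 2.11e-07; p = 0.00562 with an estimated correlation). S100a8 and S100a9 were listed at 0 in Botox 2, a library that lacked many weak genes. In Botox 4 S100a8 was at 3.22 TPM, near the 3.27 TPM of PBS 1. Whether missing weak genes led to that call was not tested. Without a filter on low values only the cholesterol list, described with the lists, was called. The immunoglobulin gene Igkc was at 1.15, 0.484 and 15.2 TPM in the PBS libraries and was listed at 0 in the 4 Botox libraries. The Schwann cell or neuron marker with the highest TPM was Pmp22, which is also expressed outside nerve, at 1.43 ± 0.0913 and 1.07 ± 0.563 TPM. Snap25, the vesicle fusion gene whose protein botulinum toxin type A cuts, was listed at 0 in 6 libraries and at 0.00305 TPM in Botox 1.

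Most transcripts had lower TPM after Botox, and no single gene passed the test. Of 11260 genes, 93.8% had a negative log2 fold change, with a median of -0.46 on the log2(TPM + 1) scale, which was -0.26 without Botox 4 and -0.15 without Botox 2 and Botox 4. In 2518 genes (22.4%) all 4 Botox libraries lay below all 3 PBS libraries, and in 17 genes (0.15%) they lay above. Chance gives 2.86% on each side for a gene taken alone, but genes share the scale of their library. Size factors were 0.435 to 1.17 in the Botox libraries and 1.20 to 1.40 in the PBS libraries. These counts are therefore not separate evidence for each gene. With limma, 0 genes were higher and 0 were lower after Botox at a Benjamini-Hochberg adjusted p of 0.05, while 15 were higher and 830 lower at an unadjusted p under 0.05. With median-of-ratios size factors the median was -0.04, and the unadjusted counts were 255 higher and 240 lower. Quantile normalization gave 395 and 284. Only 1 gene was called under these scalings, the processed pseudogene Gm16304, at a log2 fold change of 1.88 ± 0.12 (SE; limma adjusted p = 0.00988 with size factors). It falls outside the naming rule and was picked after its values were seen. Without Botox 1 the adjusted counts were 3 higher and 104 lower, and without any other single library both were 0. Of these 107 genes, with a median of 2.57 TPM after PBS, 57 were pseudogenes and 1 was protein-coding, Mettl21c, which falls outside the naming rule and was picked after its values were seen. The Botox libraries left then were those lacking the most weak genes, with 25.9%, 6.27% and 30.9% of protein-coding genes expected at 10 to 30 reads missing in Botox 2 to 4 against 0.73% in Botox 1, and 45 of the 107 were listed at 0 in all 3.

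None of the 12 genes with the smallest p that were lower after Botox was past the threshold (limma adjusted p = 0.42 for each). Clec4e, a macrophage receptor for mycobacterial and damage-derived ligands, was at 5.80 ± 1.38 TPM after PBS (SD, n = 3) and 1.83 ± 0.954 TPM after Botox (SD, n = 4), a log2 fold change of -1.31 ± 0.33 (SE). The neutrophil chemokine Cxcl2 was at 227 ± 73.8 and 86.9 ± 59.8 TPM, -1.53 ± 0.51 (SE). Platelet factor 4, Pf4, was at 4.55 ± 3.02 and 1.016 ± 0.547 TPM. Ms4a6c, a monocyte gene, was at 4.58 ± 0.991 and 1.69 ± 0.867 TPM, and Tnfsf14, which encodes the cytokine LIGHT, at 2.66 ± 0.790 and 0.883 ± 0.560 TPM. Ibsp, which encodes bone sialoprotein, was at 8.38 ± 3.84 and 2.99 ± 1.67 TPM, and the chromatin protein gene Dek at 5.30 ± 1.40 and 2.25 ± 0.711 TPM. Hmgcs1, of cholesterol synthesis, is described with its list. Zfp125, Tmsb10b, Mospd4 and Hmgb1-rs16 completed the 12, with log2 fold changes of -1.13, -2.03, -1.51 and -1.41. Zfp125, Mospd4 and Hmgb1-rs16 are pseudogenes in the deposited annotation. With size factors the log2 fold changes of the 12 ran from -0.48 for Dek to -1.54 for Tmsb10b.

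None of the 12 genes with the smallest p in the other direction was past the threshold either (limma adjusted p = 0.42 to 0.44). Their log2 fold changes ran from 0.28 to 0.58 on the deposited scale, and with size factors from 0.60 for Rpl27rt to 1.024 for Rpph1 (limma adjusted p = 0.92 for each). Nprl2, part of the GATOR1 complex that restrains mTORC1, was at 0.605 ± 0.194 TPM after PBS (SD, n = 3) and 1.24 ± 0.161 TPM after Botox (SD, n = 4), a log2 fold change of 0.49 ± 0.23 (SE). Of mitochondrial genes, Cox5b, a subunit of cytochrome c oxidase, was at 1.82 ± 0.148 and 2.78 ± 0.840 TPM, and Slirp, which stabilizes mtDNA transcripts, at 0.790 ± 0.393 and 1.56 ± 1.022 TPM. Paxx, of DNA end joining, was at 0.746 ± 0.0297 and 1.31 ± 0.729 TPM. Rpph1, the RNA of ribonuclease P, was at 5.38 ± 0.579 and 8.52 ± 4.47 TPM. Rn7s1 and Rn7s2 each had a log2 fold change of 0.28 ± 0.16 (SE) and of 0.91 with size factors, and Rn7s2 turned to -2.73e-06 with quantile normalization. BC046401, AA914427, Tmem88, Syna and Rpl27rt had log2 fold changes of 0.58, 0.52, 0.45, 0.38 and 0.32.

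**Figure D3:**
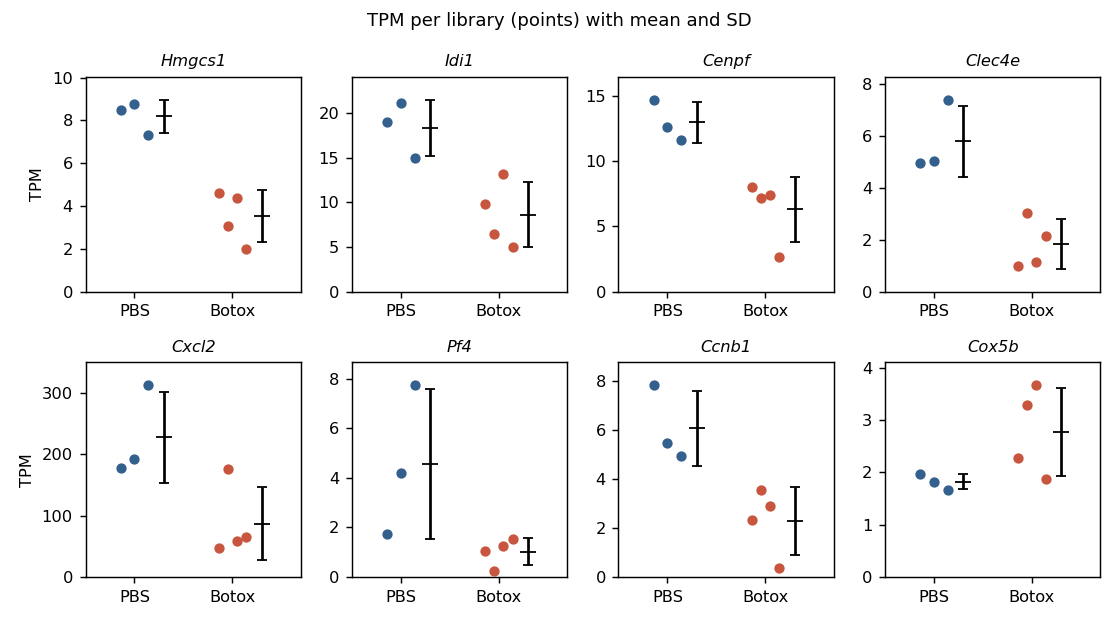
TPM of 8 named genes per library (points, linear axes from 0), with the mean and SD of each group beside them (PBS, n = 3; Botox, n = 4). Hmgcs1 lies at 7.33 to 8.76 TPM in the PBS libraries and at 2.01 to 4.61 TPM in the Botox libraries.

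Cholesterol and fatty acid synthesis was the 1 list of 31 that passed the test, and it fell relative to all other genes (camera adjusted p = 0.0168), at a preset correlation. The call did not hold with an estimated correlation (camera p = 0.38), and fry gave p = 0.052 (0.30 adjusted). On the deposited scale that correlation was 0.65 for this list, and no list had a camera p under 0.33 with it. Genes share the scale of their library, so the loss of the call there decides little. With size factors the camera p with an estimated correlation was 0.17. Its median log2 fold change was -0.64, 0.19 below that of all genes, and the relative difference was -0.12 with size factors. All 24 tested members were negative and 17 lay below the all-gene median, but 0 passed over all genes and 0 when adjusted over the list alone. In 13 members every Botox library lay below every PBS library. Hmgcs1, which makes HMG-CoA, was at 8.19 ± 0.758 TPM after PBS (SD, n = 3) and 3.52 ± 1.21 TPM after Botox (SD, n = 4), -1.06 ± 0.33 on the log2 scale (SE). Idi1, the isopentenyl diphosphate isomerase, was at 18.3 ± 3.11 and 8.597 ± 3.66 TPM, -1.08 ± 0.39 (SE). With size factors Hmgcs1 and Idi1 were at -0.55 and -0.50. Both lie on chromosome 13 in mm39, Hmgcs1 (ENSMUSG00000093930) at 120151915 to 120169797 and Idi1 (ENSMUSG00000058258) at 8935537 to 8942488, as the deposited table gives them for the whole gene, introns included. The call was also lost without PBS 2 (adjusted p = 0.47), Botox 2 (0.38) or Botox 1 (0.078), and with size factors and without both Botox 2 and Botox 4 (0.051).

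No mitochondrial list passed the test. The 13 protein genes of mtDNA made up 6.12% ± 0.412 of TPM after PBS (SD, n = 3) and 6.37% ± 3.28 after Botox (SD, n = 4), a difference of 0.24 percentage points (exact permutation p = 0.97). The Botox libraries ranged from 3.16% in Botox 3 to 10.8% in Botox 4, and without Botox 4 the difference was -1.23 percentage points. As a share of protein-coding TPM the difference was 9.43 points (35.8% ± 1.74 and 45.3% ± 22.3; exact permutation p = 0.63), without the 10 highest other genes 8.61 points (exact permutation p = 0.51) and as a share of estimated reads 2.75 points (exact permutation p = 0.63). As a list their median was 0.11 above that of all genes (camera adjusted p = 0.57), 0.33 above with size factors and at -0.05 from it with quantile normalization. mt-Nd4l was at 620 ± 102 and 263 ± 204 TPM, with 563 TPM in Botox 1 and 126 to 220.2 TPM in the other Botox libraries. mt-Nd3 was at 188 ± 16.9 and 106 ± 59.8 TPM, with 188 TPM in Botox 2, and mt-Nd6, the gene on the light strand, was at 340 ± 53.8 and 218 ± 83.1 TPM. mt-Co1 was at 24559 ± 3086 TPM after PBS and at 19594, 28110, 13623 and 54890 TPM in Botox 1 to 4. Without Botox 2 and Botox 4 the list was called lower, 0.61 below all genes (camera adjusted p = 8.27e-06; p = 0.21 with an estimated correlation), and without Botox 3 it was called higher (4.49e-06; p = 0.069 with an estimated correlation). Array weights also called it lower (0.030; p = 0.38 with an estimated correlation). They counted Botox 2 and Botox 4 least, with weights of 0.430 and 0.0796 against 0.608 to 6.10 in the other libraries. Nuclear genes of complex I had a median 0.20 above that of all genes (camera adjusted p = 0.24), and 0.08 above with size factors. Their members with the smallest p were negative on the deposited scale: Ndufab1 at -0.59 ± 0.27, Ndufb11 at -0.78 ± 0.49 and Ndufb9 at -0.41 ± 0.36 (log2 fold change ± SE). With size factors Ndufab1 and Ndufb11 were at -0.32 and -0.28. Ndufb9 was at 0.00 with size factors and 0.09 with quantile normalization, under which the list was called higher (adjusted p = 0.034; p = 0.055 with an estimated correlation). The TCA cycle list was at -0.04 from all genes (camera adjusted p = 0.71) and at 0.00315 with size factors. Its members Idh1, Pdha1 and Idh3a were at -0.87 ± 0.32, -1.01 ± 0.44 and -0.68 ± 0.33 on the deposited scale, and at -0.48, -0.47 and -0.26 with size factors.

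Growth and tumor cell state lists were not called. In the cell cycle list all 28 tested members were negative, and the median was at -0.02 from that of all genes (camera adjusted p = 0.42) and at -0.05 with size factors. The list was called lower with array weights (0.0016; p = 0.35 with an estimated correlation), without Botox 3 (0.039; p = 0.55) and with the GC and span trend removed (0.041; p = 0.35). Ccnb1, which encodes the mitotic cyclin B1, was at 6.07 ± 1.54 TPM after PBS (SD, n = 3) and 2.28 ± 1.37 TPM after Botox (SD, n = 4). The kinetochore gene Cenpf was at 12.96 ± 1.57 and 6.32 ± 2.48 TPM, and the mitotic kinase gene Aurka at 2.78 ± 0.0729 and 1.34 ± 0.686 TPM. With size factors the log2 fold changes of Ccnb1, Cenpf and Aurka were -0.82, -0.46 and -0.41. Stem cell and metastasis genes lay 0.26 below all genes (camera adjusted p = 0.27), with 8 of 9 members below the all-gene median. They were at -0.13 with size factors and at -0.10 without Botox 2 and Botox 4. Among them the polycomb gene Bmi1 was at 17.7 ± 5.35 and 8.36 ± 3.06 TPM, the chemokine receptor gene Cxcr4 at 9.30 ± 2.43 and 4.79 ± 1.90 TPM, and the hyaluronan receptor gene Cd44 at 9.40 ± 0.344 and 5.01 ± 2.22 TPM. With size factors the log2 fold changes of Bmi1, Cxcr4 and Cd44 were -0.47, -0.29 and -0.36. Genes of the cytosolic ribosome lay 0.02 above all genes (camera adjusted p = 0.57). With size factors they lay 0.14 above and were called (adjusted p = 0.0189; p = 0.27 with an estimated correlation), as they were without Botox 2 and Botox 4 (6.25e-05; p = 0.28 with an estimated correlation). Rpl4, Rpl15 and Rps16 had log2 fold changes of -1.08 ± 0.50, -1.07 ± 0.56 and -0.70 ± 0.37 (SE) on the deposited scale, and of -0.48, -0.47 and -0.26 with size factors.

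Nerve and immune lists were not called either. Of 35 genes for transmitter receptors and vesicle release, 7 were expressed highly enough to be tested, with a median at -0.04 from that of all genes (camera adjusted p = 0.88) and at 0.00548 with size factors. They included Chrnb1, Vamp3 and Snap29 at -0.65 ± 0.36, -0.76 ± 0.43 and -0.50 ± 0.29 (log2 fold change ± SE). With size factors these 3 genes were at -0.215, -0.19 and -0.03. Neurotrophins, axon guidance genes and their receptors lay 0.11 above all genes (camera adjusted p = 0.90), with Efnb1, Efnb2 and Nrp2 at -0.67 ± 0.31, -0.70 ± 0.40 and -0.58 ± 0.37. Size factors brought Efnb1, Efnb2 and Nrp2 to -0.18, -0.17 and -0.08. Antigen presentation genes lay 0.04 above all genes (camera adjusted p = 0.24) and 0.23 above with size factors (0.055). The list was called higher without PBS 3 (0.00865; p = 0.29 with an estimated correlation) and with protein-coding genes only (0.0239; p = 0.34 with an estimated correlation). H2-D1, a class I heavy chain gene, was at 278 ± 51.4 TPM after PBS (SD, n = 3) and 191 ± 92.7 TPM after Botox (SD, n = 4), B2m was at 146 ± 20.005 and 102 ± 51.002 TPM, and the peptide trimming gene Erap1 was at 2.81 ± 0.412 and 1.59 ± 0.846 TPM. With quantile normalization H2-D1 and B2m turned to 0.01 and 0.04 on the log2 scale. Macrophage and monocyte markers lay 0.24 below all genes (camera adjusted p = 0.71) and were at -0.10 with size factors. On the deposited scale Cd68, Mrc1 and Fcgr1 were at -1.04 ± 0.47, -0.61 ± 0.29 and -0.66 ± 0.32, and with size factors at -0.46, -0.13 and -0.21. Without Botox 2 and Botox 4 these markers were called lower, 0.92 below all genes (camera adjusted p = 0.000299; p = 0.29 with an estimated correlation), as they were with array weights (2.63e-05; p = 0.19 with an estimated correlation). Because array weights counted the same libraries least, that fit is not separate evidence. Targets of the inflammatory factor NF-kB and cytokines were at -0.03 from all genes (camera adjusted p = 0.93) and at 0.03 with size factors, and were called lower without PBS 1 (0.00589; p = 0.19 with an estimated correlation). Markers of erythrocytes and platelets, at -0.26 from all genes with 5 tested members (camera adjusted p = 0.93), were also called lower without PBS 1 (0.0275; p = 0.074 with an estimated correlation). Across the 30 lists that were not called the camera adjusted p ran from 0.24 to 0.95, and all 31 list medians were negative on the deposited scale. For the nuclear genes of complexes II to IV and for replication-dependent histones, camera's direction was up while the median was at -0.11 and -0.17 from that of all genes. With size factors the histone median was at 0.03.

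**Figure D4:**
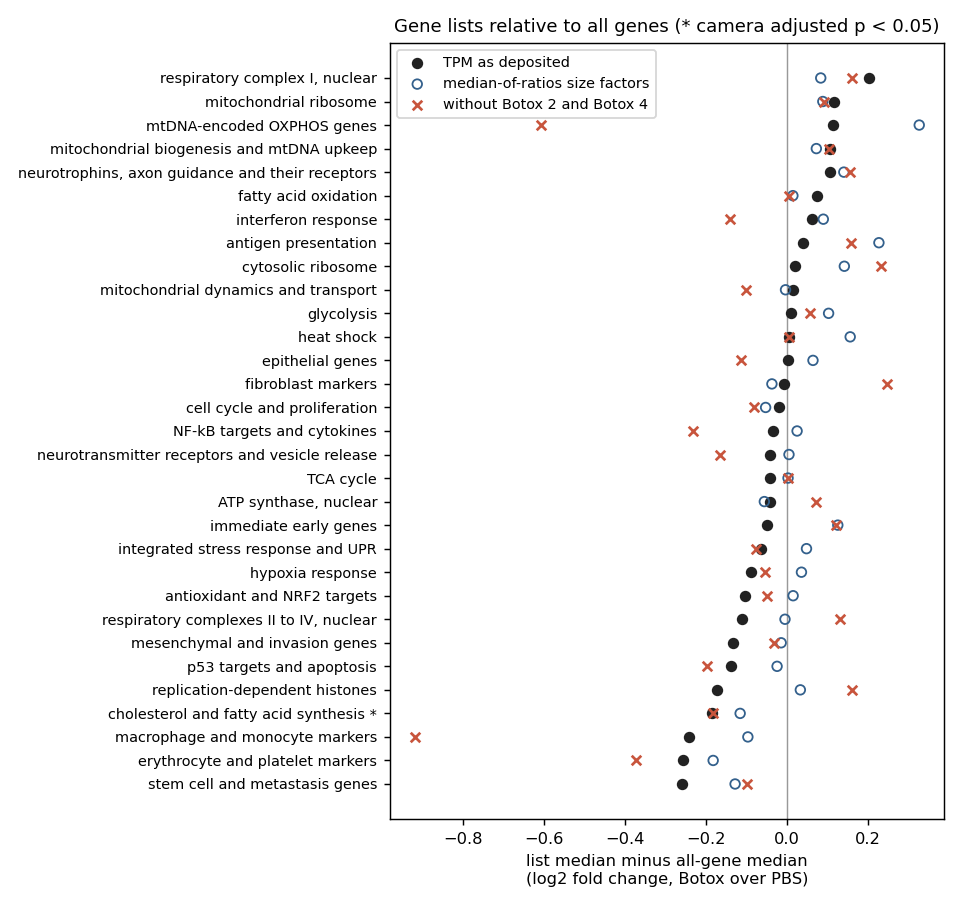
Median log2 fold change (Botox over PBS) of each of 31 gene lists minus that of all tested genes, on the deposited scale (filled), with median-of-ratios size factors (open) and without Botox 2 and Botox 4 (crosses). The cholesterol list, the 1 with a camera adjusted p under 0.05 on the deposited scale, lies at -0.19, -0.12 and -0.18, while the mtDNA list lies at 0.11, 0.33 and -0.61.

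In the authors' deposited table of KEGG gene sets, all 227 ratios of B to C were below 1, from 0.540 to 0.837 with a median of 0.683, and 220 sets had a false discovery rate under 0.05. The smallest p-value in the authors' deposited table was 1.31e-24, for platelet activation with 49 genes. How genes and libraries entered that test is not given in the sources used here. If the genes of a set counted as replicates, such values do not measure the spread between mice. The 220 sets are therefore not evidence beyond the shift that most genes shared. The lowest ratio in the authors' deposited table was that of the amoebiasis set, 0.540. Some sets had names close to those of the lists above, and those given here are examples. In the authors' deposited table steroid biosynthesis was at 0.576 and terpenoid backbone biosynthesis at 0.601, but fatty acid biosynthesis, with 2 genes, at 0.718. The TCA cycle was at 0.652, oxidative phosphorylation at 0.706, glycolysis at 0.715 and antigen processing at 0.693 in the authors' deposited table. Of nerve sets in the authors' deposited table, the cholinergic synapse was at 0.608 and the synaptic vesicle cycle at 0.719. The highest ratio in the authors' deposited table, 0.837, was that of ribosome biogenesis. In the fits to the expression table the typical Botox to PBS ratio was 0.728 over all tested genes on the log2(TPM + 1) scale. Over tested protein-coding genes it was 0.621 on the log2 scale of the deposited values. That scale adds no further pseudocount but keeps the authors' small constant, so genes without reads enter it at that constant. Of the 227 ratios in the authors' deposited table, 182 lay below the first value and 38 below the second. The p-value that the column name gives for disruption by treatment was 0.296 or higher in every set of the authors' deposited table.

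**Figure D5:**
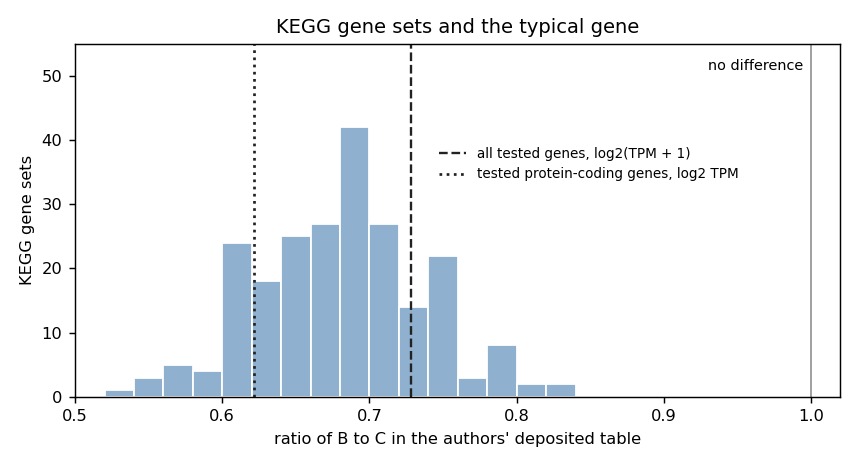
Number of KEGG gene sets by ratio of B to C in the authors' deposited table (bins of 0.02). Lines show the typical Botox to PBS ratio of all tested genes (dashed, 0.728) and of tested protein-coding genes (dotted, 0.621). The dotted value has no pseudocount beyond the constant that the authors added. All 227 sets lie below 1, and both typical ratios lie within their range.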

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

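In 103 checks of the 4 Botox libraries for a value far from the other 3, over values per library, mean list levels and named genes, 5 stood apart, where chance gives about 5.15. The 3 PBS libraries were too few for this check. In Botox 4 the mean log2(TPM + 1) of the hypoxia response list was 2.25, against 2.84 to 2.96 in the other Botox libraries. The p53 target and apoptosis list was at 2.09 in Botox 4, against 2.81 to 2.90. Cenpf was at 2.64 TPM in Botox 4 and at 7.16 to 8.04 TPM in the others. Cxcl2 was at 175.8 TPM in Botox 2 and at 47.4 to 65.6 TPM in the others. Mospd4, a processed pseudogene, was at 2.94 TPM in Botox 1 and was listed at 0 in the others. The number of such values is that of chance, and none of them was weighed further.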

How the results depend on the processing

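The alternatives that leave out Botox 2 and Botox 4, keep only protein-coding genes, remove the 7SL genes or remove the GC and span trend were chosen after the data were seen. Higher and lower counts stayed at 0 under both other pseudocounts, the stricter filter, removal of mtDNA genes and limma without trend. Without a filter 22 genes were lower. Median-of-ratios size factors, quantile normalization and array weights each called 1 gene higher, as did size factors with the GC and span trend removed. With 1 library left out, the higher count ran from 0 to 3 and the lower from 0 to 104, both highest without Botox 1. Lists called were 2 with size factors, 2 with quantile normalization, 4 with array weights, 0 with a correlation estimated per list and 0 to 4 with 1 library left out (0 without PBS 2, Botox 1 or Botox 2; 4 without Botox 3; 3 without PBS 1 or PBS 3). Leaving out Botox 2 and Botox 4 gave 4 lists, the same with size factors 3, protein-coding genes only 3, and the GC and span trend removed 2. The cholesterol list was lower than all genes in each of 23 alternatives and past the threshold in 19, with adjusted p from 0.000274 to 0.47, all at the preset correlation. Leaving out Botox 4 and using libraries 1 to 3 of each group without a block are the same fit, counted under both names. The alternatives share most of their libraries, so these counts are not independent. With an estimated correlation each of the 19 calls was lost (p = 0.069 to 0.44). The median of all genes was -0.0379 with size factors, 0.000207 with quantile normalization, -0.0537 with the GC and span trend removed and -0.00498 with size factors without Botox 2 and Botox 4, and kept its sign in the others.

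The mtDNA share difference ran from -1.23 to 1.31 percentage points with 1 library left out, negative without Botox 4, and was -2.13 without Botox 2 and Botox 4 (exact permutation p = 0.20, the smallest possible there). Of 1229 values of 56 named genes under the alternatives, 12 changed sign and 1, Mospd4 without Botox 1, passed the threshold. With quantile normalization Rn7s2 was at -2.73e-06, Ndufb9 at 0.0944, H2-D1 at 0.0139 and B2m at 0.0438. With size factors and without Botox 2 and Botox 4, Ndufb9 was at 0.0174, Nrp2 at 0.0718, Chrnb1 at 0.0322, H2-D1 at 0.101 and B2m at 0.0403. With the GC and span trend removed mt-Nd3 was at 0.0614, mt-Nd6 at 0.247 and B2m at 0.0210. The causes of these changes were not tested.

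Same-numbered libraries did not deviate together (r = 0.09, -0.03 and -0.18), so the numbers were not taken as pairs. With a replicate block over libraries 1 to 3 of each group, 0 genes were higher, 0 lower and 1 list, the cholesterol list, was called, as without the block in the same 6 libraries. That call was lost with an estimated correlation (p = 0.42 with the block and 0.27 without it).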

Other observations

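The tests of explanations below were chosen after the results they bear on were seen, except the counts over splits of the libraries and the test of missing reads, which were set beforehand.

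Histone, early response and interferon genes were not called as lists with all 7 libraries. H2ac8, a replication-dependent histone gene, was at 38.9 ± 8.35 TPM after PBS (SD, n = 3) and 17.5 ± 17.8 TPM after Botox (SD, n = 4). Without Botox 3 the histone list was called lower (camera adjusted p = 0.0253; p = 0.42 with an estimated correlation). Fos and Egr1, which respond within minutes to handling and growth signals, were at 925 ± 14.5 and 357 ± 26.5 TPM after PBS and 526 ± 282 and 205 ± 113 TPM after Botox, and all 23 tested genes of the early response list were negative, with a median at -0.05 from that of all genes (camera adjusted p = 0.93) and at 0.13 with size factors. The interferon genes Ifit1 and Ifi44 were at 6.6002 ± 1.11 and 7.95 ± 1.47 TPM after PBS and 2.83 ± 1.64 and 4.21 ± 1.25 TPM after Botox, while the list of 27 tested genes lay 0.06 above all genes (camera adjusted p = 0.93) and at -0.14 without Botox 2 and Botox 4. Without PBS 3 it was called higher (0.0232; p = 0.36 with an estimated correlation).

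In Botox 2 and Botox 4, 3.01% and 2.44% of the detected genes had 1 to 4 estimated reads, against 14.0% in Botox 3 and 20.4% to 23.8% in Botox 1 and the PBS libraries. Shallower sequencing is argued against by 10.5 M estimated reads in Botox 2, within the 8.57 to 13.6 M of the other 5. A minimum set by the authors is argued against because genes with 1 to 4 reads were still present, 2.44% in the lower of both. Of protein-coding genes expected from the PBS libraries at 10 to 30 reads, 25.9% had none in Botox 2 and 30.9% in Botox 4, against 6.27% in Botox 3, 0.73% in Botox 1 and 0.33% to 0.53% in the PBS libraries. This is consistent with few distinct RNA molecules that were each read many times, a hypothesis, and whether fewer cells were sorted after Botox stays open as an untested biological explanation.

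Most genes had lower TPM after Botox, with a median log2 fold change of -0.46. Without Botox 4 the median was -0.26 (SE 0.11), and without Botox 2 and Botox 4 it was -0.15 (SE 0.07). Both values lay more than 2 standard errors below 0. With so few libraries left these standard errors are uncertain, so whether Botox 4 or both libraries account for all of the shift could not be settled. With the 7SL genes removed and each library rescaled the median was -0.24 (SE 0.17). A larger share of 7SL RNA cannot be told apart from a remaining shift because that value lies between 1 and 2 standard errors from 0. Of the 35 splits of the libraries into 4 and 3, 3 gave a median as far from 0, up to 0.53 when Botox 3 was put with PBS, so chance could not be excluded. With 0 genes past the threshold in the real split, a count over the 35 splits decides nothing. The highest other count, 181, came from putting Botox 1 with the PBS libraries. In correlations of log2(TPM + 1) over the tested genes, however, Botox 2 and Botox 4 stood furthest apart, at r = 0.865 to 0.921 with every other library. With the PBS libraries Botox 1 was at 0.960 to 0.969 and Botox 3 at 0.937 to 0.946. Botox 1 was the 1 Botox library with nearly as few missing genes as the PBS libraries. Of the 181 genes, 172 were not protein-coding, 64 were listed at 0 in all of Botox 2 to 4 and 115 in both Botox 2 and Botox 4. The loss of weak genes in Botox 2 to 4 therefore stays open beside a weaker response of Botox 1, neither of them tested.

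Cholesterol and fatty acid synthesis genes were called lower relative to all genes at the preset correlation (camera adjusted p = 0.0168) and not with an estimated one (p = 0.38), so members that vary together between libraries remain a candidate explanation. On the deposited scale the estimate also holds the library scale that all genes share, so it cannot single out these members. Size factors and removal of the trend with GC content and span moved the list's offset from all genes by only part of its size. Averaged over libraries, the offset was -0.23 (SE 0.06), and size factors moved it by 0.0775 (SE 0.0451). Removal of that trend moved the remaining -0.15 (SE 0.07) by 0.00668 (SE 0.0151), to -0.14 (SE 0.078). The camera adjusted p was 0.0189 and 0.00123 (p = 0.17 and 0.14 with an estimated correlation). The trend thus accounts for little of the offset. The remainder after both steps lay less than 2 standard errors from 0, so it cannot be told from no difference. The few molecules of Botox 2 and Botox 4 stay open. Without both, the camera adjusted p was 0.0146 (p = 0.069 with an estimated correlation) and the list's offset -0.19 (SE 0.055). With size factors and without both, the camera adjusted p was 0.051 and the offset -0.15 (SE 0.063), so the call was lost with little change of the offset. Without Botox 2 alone the camera adjusted p was 0.38. So few libraries are left without both that the offsets cannot settle the question. Of the 35 splits, 2 gave an adjusted p as small for this list (1.77 as -log10 in the real split, 1.81 in the other, with Botox 3 put with PBS), and 34 called at least 1 list, up to 9 against the 1 found here, so chance could not be excluded. An effect of denervation on sterol synthesis stays an open, untested hypothesis.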
